A study of Mus musculus with 2 samples.

How the data were processed

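DNase-seq of newborn mouse thymus was measured in 2 biological replicates of 1 group, per the labels. The labels give both replicates the same donor and different biosamples, so the SD over n = 2 is the spread between these samples, part of which may be technical. For each replicate the authors deposited a list of peaks and a list of hotspots on mm10, called for that library alone and not on pooled replicates, per the text that accompanies the files. The peak and hotspot callers, their thresholds, the aligner and the read totals are not given in the sources used here. The labels name the sequencing instruments of replicate 2 alone. Depth is therefore unknown, and no value could be scaled by it.

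The deposited peaks carry a score per peak in whole numbers from 1 to 150, never above the peak width of 150 bp. What the score counts is not stated in the sources used here, and it was used to rank and filter peaks within each list. A fixed upper limit compresses differences among the strongest peaks. The deposited hotspots carry a −log10 of a q-value, lowest at 1.30, with no value between 6 and a cap of 100, and 45.9% of hotspots in replicate 1 and 43.5% in replicate 2 were at the cap. Hotspots were ranked by that value alone, so the strongest of them cannot be told apart by rank. The hotspots also carry a deposited display score, which was not used.

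Positions were compared with the GRCm38 sequence, and all peaks and hotspots on the main chromosomes (autosomes, X and Y) lay within its lengths. Annotation was GENCODE M21, with 21853 protein-coding genes and 54361 transcription start sites (TSSs). Positions are printed counting from 1. Peaks off the main chromosomes entered the overlap of replicates and were left out of annotation. Overlap was at least 1 bp. A shared peak is a peak of replicate 1 that overlaps a peak of replicate 2. Random placement kept each peak's chromosome and length and was repeated 20 times. A promoter peak has its midpoint within 1000 bp of a protein-coding TSS, and all others are distal. Distal peaks were split into exon, intron and intergenic by the midpoint, and were assigned to the nearest coding TSS within 100 kb.

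Each gene list was set against 10000 random lists of the same size, matched gene by gene on deciles of territory length, the sequence nearer to the gene's TSSs than to any other within 100 kb. For promoter peaks the match was on deciles of CpG count within 500 bp of the TSS. A list was called above or below past the 97.5th or under the 2.5th percentile. Genes are not replicates, and the percentile describes these libraries. Of 14 erythroid genes listed, 13 were in the annotation. Consensus sequences were searched on both strands in the central 150 bp of peaks and in flanking windows of the same width 1000 bp away that overlapped no peak, with a shuffle of each peak that keeps its dinucleotides as the alternative background.

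The 17 lists, 15 consensus sequences, alternatives and the rule for naming genes were set before the data were examined. The rule allows the text to name the 20 genes with the most distal shared peaks, the 4 members of each list with the most, list members whose promoter result goes against their list, the genes at the 10 strongest shared peaks, and a fixed set of thymus genes with the T cell receptor loci. Alternatives were a reciprocal overlap of 50%, the stronger 50% of peaks, equal numbers of peaks, hotspots for peaks, a promoter window of 2500 bp, start sites of all biotypes, a limit of 50 kb, no matching, other backgrounds and each replicate alone.

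The steps were tested on simulated data. Replicate lists with 20%, 50% and 80% of peaks planted as shared gave 22.3%, 52.3% and 81.4%, random overlaps included. Of 200 simulated lists of 16 genes, 1% with no change were above the 97.5th percentile, as were 39% with a 2-fold and 83.5% with a 4-fold rise, so a list of this size can hold a 2-fold rise without being called. Simulated windows had the RUNX consensus in 15.9%, for 16.0% by construction. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.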

Results

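DNase-seq was used to map open chromatin in the thymus of newborn mice (strain B6NCrl, postnatal day 0, males and females pooled). The thymus is the organ in which T cells mature, and DNase I cuts chromatin preferentially where regulatory DNA is accessible. The series held 1 group of 2 biological replicates, labelled with the same donor and different biosamples, each with a list of peaks of 150 bp and a list of wider enriched regions called hotspots, on mouse build mm10 (GRCm38). Replicate 1 had 154812 peaks and 135932 hotspots, and replicate 2 had 139702 peaks and 121064 hotspots. Read totals were not given in the sources used here, so the sequencing depth behind each list is unknown. With a single group there were no conditions to compare. The values below describe these libraries, the replicates against each other, and gene groups and sequence motifs against matched backgrounds, without p-values.

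Open chromatin was largely the same in both thymus replicates. Of all peaks, 71.0% ± 5.29 (SD, n = 2) overlapped a peak of the other replicate by at least 1 bp, 67.3% in replicate 1 and 74.8% in replicate 2. Random placement of the same peaks gave 1.73% and 1.92%. The T cell co-receptor genes Cd4, Cd8a and Cd8b1, the recombinase genes Rag1 and Rag2, and the kinase gene Lck each had a promoter peak in both replicates. Peak strength was taken from the score the authors deposited for each peak, which ran from 1 to 150 in both lists. Across 96372 peaks that overlapped 1 to 1, the scores had a Spearman's rho of 0.917, a value across peaks, which are not independent replicates. Sharing rose with the score. In replicate 1, 13.2% of the lowest decile of peaks by score and 98.3% of the highest decile had a counterpart, and in replicate 2 the shares were 18.96% and 99.1%. Peaks without a counterpart numbered 50648 in replicate 1 and 35258 in replicate 2, and 27.9% and 13.7% of them overlapped a hotspot of the other replicate. Hotspots covered 1.78% ± 0.0806 (SD, n = 2) of the main chromosomes, and every peak overlapped a hotspot of its own replicate.

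**Figure D1:**
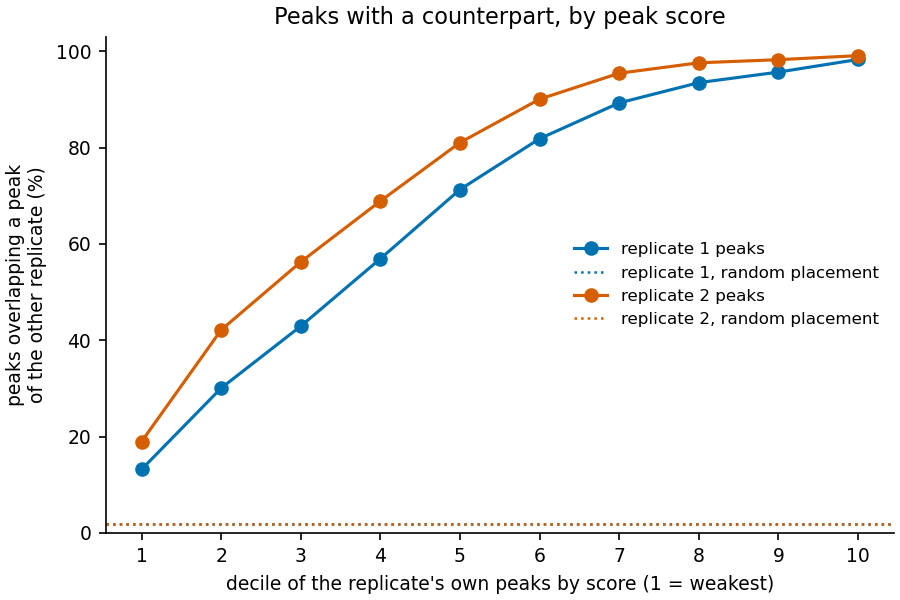
Percent of peaks that overlap a peak of the other replicate (vertical axis) for each decile of a replicate's peaks ranked by score (horizontal axis, 1 the weakest), with points for replicate 1 (blue) and replicate 2 (orange) and dotted lines for random placement. The share runs from 13.2% to 98.3% in replicate 1 and from 18.96% to 99.1% in replicate 2.

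Of promoters, exons, introns and intergenic sequence, promoters were the most enriched in peaks. Peaks within 1000 bp of the transcription start site (TSS) of a protein-coding transcript made up 23.1% ± 0.490 of peaks (SD, n = 2), 9.48 ± 0.201 times the share of the genome in such windows. Exons outside promoters held 4.82% ± 0.345 of peaks, introns 36.1% ± 0.285 and intergenic sequence 35.9% ± 0.430. The ratio to the genome share was 1.60 ± 0.114 for exons, 1.05 ± 0.00828 for introns and 0.598 ± 0.00715 for intergenic sequence, differences larger than the spread between replicates. In alternatives chosen after the data were seen, the promoter ratio was 5.65 with a window of 2500 bp, 4.99 with start sites of all biotypes and 12.5 with the stronger 50% of peaks, each time the highest of the 4 ratios. The intron ratio was on both sides of 1, at 0.956 with 2500 bp and 0.943 with the stronger 50%. The 10 strongest shared peaks of the main chromosomes were all at promoters. They lay at Hjurp, a centromere histone chaperone gene, at the chaperone genes Hspa8, Hspa14 and Tcp1, at the initiation factor gene Eif2b4, at the deubiquitinase gene Usp22, and at Ints7, Bbip1, Cfap20 and Smyd4. The peak at Hjurp, on chromosome 1 from 88277556 to 88277705 in an exon, was centred 2 bp from the TSS and scored 146 and 149. A promoter peak was found for 64.4% ± 0.398 (SD, n = 2) of 21853 protein-coding genes, and for 62.2% in both replicates. With a window of 2500 bp, or with the stronger 50% of peaks, the share of peaks at promoters and the share of genes with a promoter peak moved by more than the spread between replicates, by under 1.5 times.

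Of the 4 lists of T cell genes, 3 were called above matched random lists by distal open sites. These were T lineage transcription factors, T cell receptor and signalling genes, and early thymocyte genes. The list of effector and regulatory T cell genes was not called, with a mean of 5.25 against a random median of 3.50 (percentile 89.6). A list of 16 simulated genes could hold a 2-fold rise without being called, so a smaller rise in this list is not excluded. Distal shared peaks, those more than 1000 bp from a coding TSS and found in both replicates, were assigned to the nearest coding TSS within 100 kb, and 68872 of 78719 could be assigned. The mean over all genes was 3.15 per gene, and the median 1. The 19 T lineage transcription factors had a mean of 23.7 distal shared peaks, against a median of 4.95 in 10000 random lists matched on territory length, and lay at the 100th percentile. All 19 had at least 1 distal shared peak. The 20 genes of the T cell receptor complex and its signalling had a mean of 13.5 against 3.30, also at the 100th percentile. The 16 genes of early thymocytes and recombination had a mean of 8.75 against 3.38 (percentile 99.9). In each replicate's own list these 3 groups were at percentile 99.5 or above.

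Among the transcription factors, Runx1 had 45 distal shared peaks, Lef1 42, Tcf7 36 and Ikzf1 35. Bcl11b, which is needed for commitment to the T lineage, had 32, Satb1 had 22 and Gata3 had 15. Tcf7, which encodes the factor TCF1, lies on chromosome 11 from 52252371 to 52283014 and held 55.8 distal shared peaks per 100 kb of its territory. The strongest of them lay between 52314196 and 52314345, in intergenic sequence 31.3 kb upstream of the nearest Tcf7 TSS, and ranked above 98.3% of peaks in replicate 1 and 98.4% in replicate 2. The strongest distal shared peak of Bcl11b lay in one of its introns, on chromosome 12 from 107964816 to 107964965, with scores of 125 and 124. Bcl11b had 44 distal peaks in replicate 1 and 70 in replicate 2.

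Within the T cell receptor and signalling group, Prkcq, a protein kinase C gene, had 32 distal shared peaks, the adhesion receptor gene Cd2 had 29, the phosphatase gene Ptprc (CD45) 23 and the zeta chain gene Cd247 19. Cd3e had 13 and Lck 7. The co-receptor genes differed in number, with 12 for Cd8a, 8 for Cd8b1 and 4 for Cd4. The strongest distal shared peak of Cd4 lay in an intron of Cd4, on chromosome 6 from 124885276 to 124885425, 2.87 kb from the TSS. That of Cd8a lay 3.796 kb upstream of its TSS, on chromosome 6 from 71369556 to 71369705, in an intron of the non-coding gene Gm44174, with scores of 127 and 139. Replicate 2 had more distal peaks than replicate 1 at both Cd8 genes, 27 against 14 at Cd8a and 28 against 9 at Cd8b1.

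**Figure D2:**
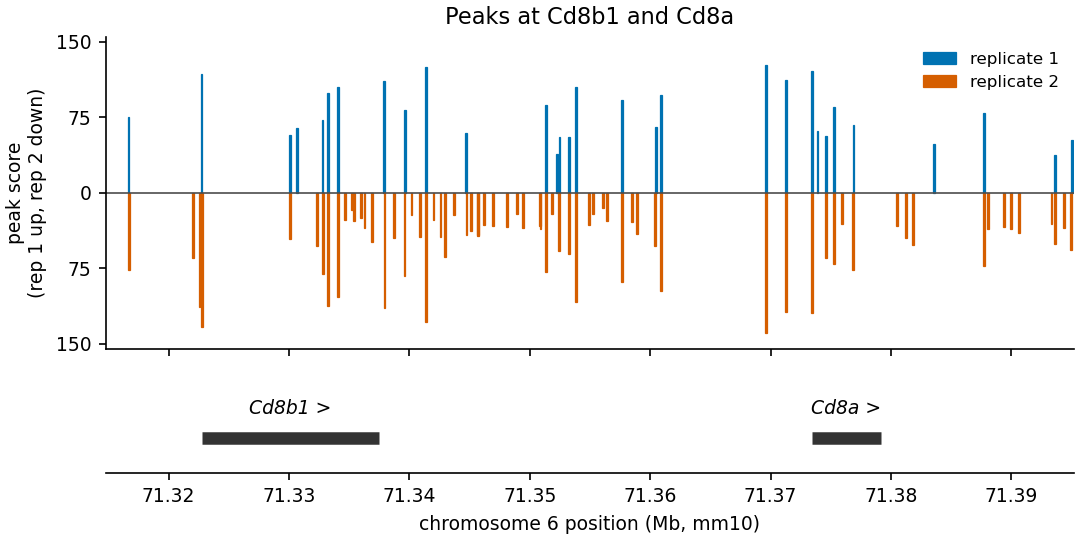
Peaks of replicate 1 (blue, upward) and replicate 2 (orange, downward) at Cd8b1 and Cd8a on chromosome 6, by position in Mb (horizontal axis, mm10) and deposited score (vertical axis), with gene bodies as dark bars and the direction of transcription as an arrowhead. Cd8a has 12 distal shared peaks and Cd8b1 8, and replicate 2 has additional weaker peaks.

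In the early thymocyte group, the Notch target gene Hes1 had 27 distal shared peaks, Cd44 17, Notch3 16 and Notch1 14. Dntt, which encodes the terminal transferase that adds nucleotides at receptor gene junctions, had 9, and Ptcra, which encodes the pre-T cell receptor alpha chain, had 2. The recombinase genes had few distal shared peaks, 4 for Rag1 and 1 for Rag2, in territories of 10.3 kb and 3.64 kb. Their strongest promoter peaks ranked above 95.7% of peaks in both replicates for Rag1 and above 94.1% and 92.5% for Rag2. The strongest promoter peak of Dntt ranked lower, above 47.2% and 54.9% of peaks.

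The remaining gene lists mostly lay within the range of random lists. The percentile was 89.6 for 12 effector and regulatory T cell genes, 91.1 for 15 myeloid genes, 80.6 for 12 B cell genes, 79.1 for 12 endothelial genes, 63.1 for 15 thymic epithelial genes, 12.8 for 13 erythroid genes and 9.32 for 12 mesenchymal genes. Cell cycle (76.1), housekeeping (96.1), hepatocyte (21.5), neuron (21.3) and striated muscle (65.7) genes were also within the central 95% of random lists. Of the remaining lists only the 9 NK cell genes stood above, with a mean of 5.89 against 2.44 (percentile 99.1). The median over these genes was 2, and 27 of their distal shared peaks lay at Klrb1c and 13 at Eomes. Without Klrb1c, an alternative added after the data were seen, the list was at percentile 76.1, and with no matching on territory length or with the stronger 50% of peaks it was at 93.4 and 95.7. The 1134 olfactory receptor genes had a mean of 0.222 against 1.57 and lay below all random lists.

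**Figure D3:**
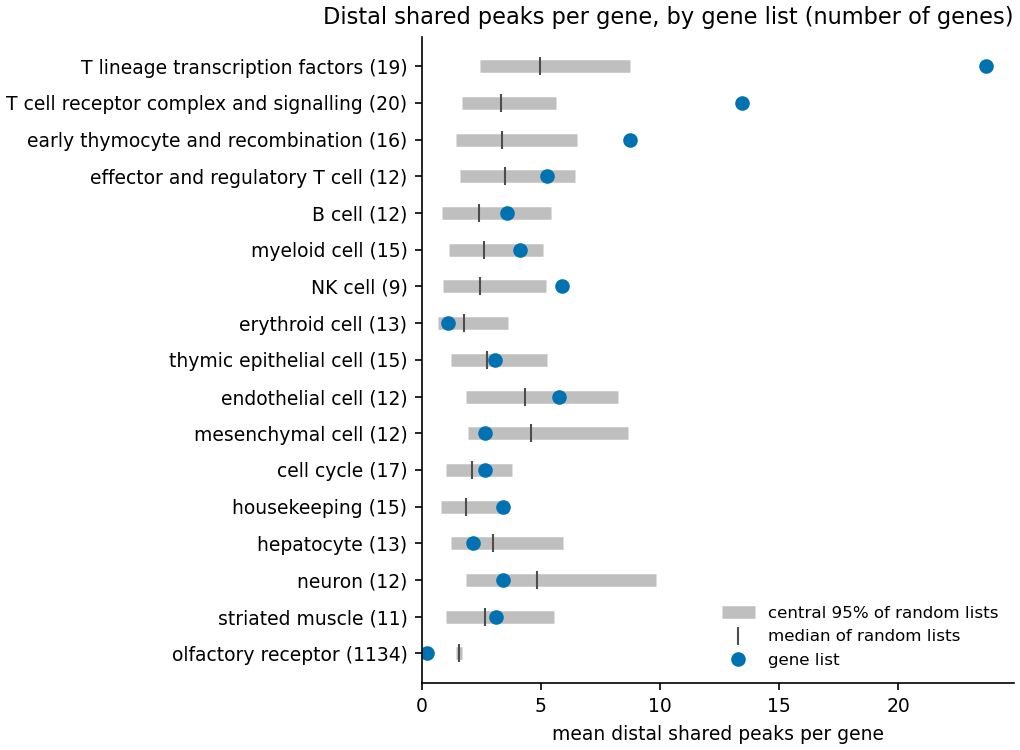
Mean number of distal shared peaks per gene (horizontal axis) for each of 17 gene lists (blue points, number of genes in brackets), with the median (tick) and central 95% (grey bar) of 10000 random lists matched on territory length. The T lineage transcription factors lie at 23.7 and the T cell receptor genes at 13.5, both to the right of their random range, and the olfactory receptor genes at 0.222 lie to the left.

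Every gene of 3 T cell lists had an open promoter. All 19 T lineage transcription factors, all 20 T cell receptor and signalling genes and all 16 early thymocyte genes had a promoter peak in both replicates, at percentiles 97.9, 100 and 100 of random lists matched on promoter CpG content. For the T lineage transcription factors the percentile was 96.5 and 96.8 in the lists of replicates 1 and 2 alone and 96.0 with a window of 2500 bp. All 17 cell cycle genes and all 15 housekeeping genes had one too, at percentiles 93.3 and 88.7. A list in which every gene had one cannot rank higher, so these percentiles reflect only how often random lists were also complete. The median random list had one at 89.5% of genes for T lineage transcription factors. For T cell receptor and early thymocyte genes this was 35% and 56.25%, and for cell cycle and housekeeping genes 88.2% and 93.3%. Of the NK cell genes, 7 of 9 had a promoter peak in both replicates (percentile 100, or 81.5 without matching on CpG). The counts were 7 of 15 for myeloid genes (percentile 96.2), 6 of 12 for B cell genes (93.6) and 6 of 12 for effector and regulatory T cell genes (85.4). They were 7 of 15 for thymic epithelial genes (5.655), 5 of 12 for endothelial genes (10.9), 5 of 12 for mesenchymal genes (29.1) and 8 of 12 for neuron genes (44.9). Erythroid genes had 4 of 13 (percentile 80.7), among them Epor, Gata1 and Nfe2, and no promoter peak was listed for the beta globin gene Hbb-bs. Hepatocyte genes had 2 of 13 (percentile 14.9), F2 and Apob. Striated muscle genes had 2 of 11, Actn2 and Ttn, at percentile 1.69, but 39.4 and 6.03 in the lists of replicates 1 and 2 alone, 5.78 with the stronger 50% of peaks and 92.4 with a window of 2500 bp. No promoter peak was listed in either replicate for Foxn1, the regulator of thymic epithelium. Olfactory receptor genes had a promoter peak in both replicates in 2.38% of cases, against 7.94% in random lists.

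The 20 protein-coding genes with the most distal shared peaks had between 44 and 85 each, a count that takes no account of territory length. Per 100 kb of territory they ranged from 3.78 at Pde4d, in 1402 kb, to 46.8 at Socs1 and 52.5 at Sfi1. Gse1, a gene for a coiled-coil protein, was first with 85, followed by the forkhead factor gene Foxp1 with 74 and by Sfi1, a centrin-binding protein gene, with 58. Signalling genes among the 20 included the Rac exchange factor gene Prex1 with 56, the phosphodiesterase gene Pde4d with 53 and Tiam1 with 51. They also included Smad3 with 49 and Socs1, a repressor of cytokine signalling, with 44. Transcription regulators of this set included Bcor with 49, Fli1 with 48, Rere with 48, Maml3 with 48 and Runx1 with 45. The others were Sept9 with 56, Ppm1h with 53, Zfp217 with 51, Mtss1 with 45, Rptor with 45, Itpr2 with 44 and Nck2 with 44. Of the 20 genes, 19 had promoter peaks in both replicates. Sfi1 had none in either, differed between replicates with 89 distal peaks in replicate 1 and 61 in replicate 2, and in the median peak 43.8% of its 31-base words recurred elsewhere on the main chromosomes or scaffolds. On the main chromosomes alone the value was 6.25%, and the scaffolds were added after it was seen.

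The T cell receptor loci were dense in shared peaks. The Tra/Trd locus, on chromosome 14 from 52427928 to 54224206, held 220 shared peaks, or 12.2 per 100 kb against 3.81 per 100 kb over the main chromosomes. The Trb locus, on chromosome 6 from 40891229 to 41558452, held 74, or 11.1 per 100 kb. The Trg locus, on chromosome 13 from 19178024 to 19352756, held 11, or 6.30 per 100 kb. In Trb, all 14 J segments, both D segments and both constant genes had a shared peak within 1000 bp of their start, as did 17 of 35 V segments. In Tra/Trd the counts were 23 of 62 J segments, 1 of 2 D segments, 59 of 134 V segments and 0 of 2 constant genes. In Trg they were 0 of 4 J segments, 3 of 7 V segments and 1 of 4 constant genes. A peak was counted for every segment that started within 1000 bp of it. Segments close together can therefore share 1 peak, and these counts also depend on the spacing of segments. The strongest shared peak of Trb lay 3140 bp from Trbv31, from 41554476 to 41554625, and ranked above 99.6% and 98.9% of peaks. Counting only peaks inside the loci, 22 shared peaks lay within 10 kb of Trbc2 and 5 within 10 kb of Trdc. For Trac the count was 3, but the locus ends with this gene. Peaks downstream of Trac were therefore not counted, and its value cannot be compared with the others.

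Of the consensus sequences of T lineage factors, all but GATA were more frequent in distal shared peaks than in flanking windows 1000 bp away. The RUNX consensus was found in 14.8% of 78719 distal shared peaks and 6.59% of flanks, a ratio of 2.25. In the replicates' own lists of distal peaks the ratio was 2.06 ± 0.0429 (SD, n = 2). The ETS consensus was found in 34.7% of peaks (ratio 2.39, own lists 2.21 ± 0.00908). The E-box sequences CAGCTG and CACCTG, bound by E proteins, had ratios of 2.29 and 2.01. These fell to 1.44 and 1.45 when the background was a dinucleotide-preserving shuffle of each peak, where RUNX was at 2.16 and ETS at 2.86. The E-box CAGATG, a comparison sequence, had a ratio of 1.42 to flanks and 1.60 to shuffled peaks, the latter above both other E-boxes. The TCF7/LEF1 consensus had a ratio of 1.49 and AP-1 1.61. The GATA consensus was less frequent in distal peaks, at 6.62% against 8.54% in flanks (ratio 0.776), but more frequent than in shuffled peaks (ratio 1.31). CTCF, a factor that bounds chromatin loops, had the highest ratio, 121, with matches in 10.04% of peaks and 0.0828% of flanks (52.0 against shuffled peaks). Among the other comparison sequences, HNF4 had a ratio of 0.698 and MEF2 1.13. Against shuffled peaks MEF2 was at 3.39, above each T lineage consensus, and HNF4 at 0.610. The HNF1 consensus had no match in 78719 distal shared peaks, which allows a share of up to 0.00381%, against 0.0131% in flanks. In shuffled peaks its share was 0.00254%, under that limit, so no deficit is shown against this background.

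Promoter peaks had another composition. NRF1 matched 4.93% of promoter shared peaks, a ratio of 42.7 to promoter flanks, against 5.505 in distal peaks. NFY had a ratio of 2.72 at promoters and 0.915 at distal sites. RUNX (1.09), CACCTG (1.09) and TCF7/LEF1 (0.606) had lower ratios at promoters than at distal sites, and ETS was at 2.09 in promoters and 2.39 in distal peaks. Promoter peaks were compared with flanks alone and not with shuffled peaks, so differences in base composition were not taken into account.

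**Figure D4:**
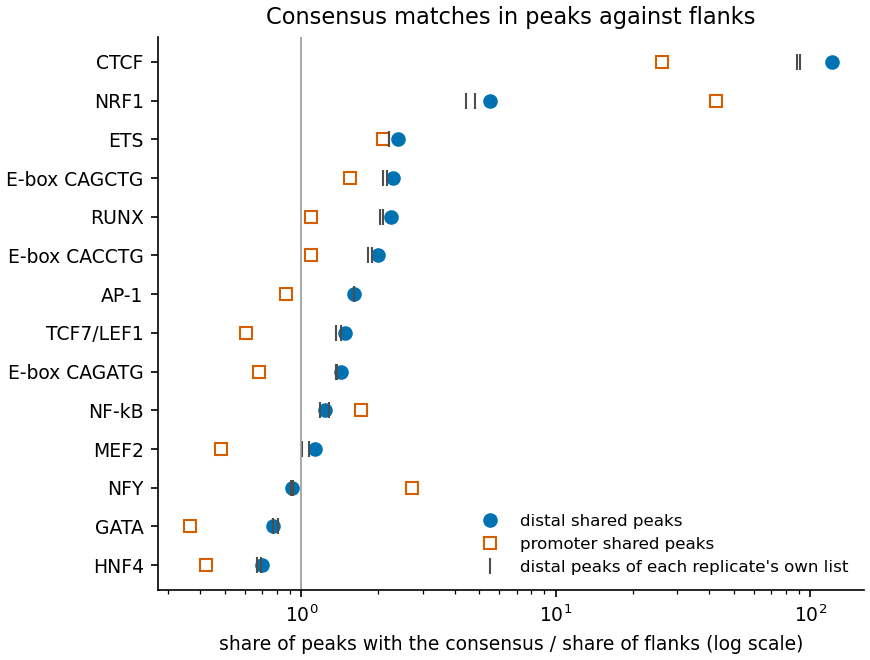
Share of shared peaks with a consensus match divided by the share of flanking windows (horizontal axis, log scale) for 14 consensus sequences, at distal peaks (blue circles) and promoter peaks (orange squares), with ticks for the distal peaks of each replicate's own list. HNF1, without a match, is left out. CTCF is at 121 in distal peaks and NRF1 at 42.7 in promoter peaks.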

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

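The counts in this part were chosen after the lists were seen. Peaks were listed on sequences that no comparison used except the overlap of replicates. Each number is above the 3 that a count of 0 allows, which does not test it against calls from background. There were no control samples. On unplaced and unlocalized scaffolds there were 420 peaks in replicate 1, of which 48.3% overlapped a peak of replicate 2, and 306 in replicate 2, of which 64.7% overlapped a peak of replicate 1. On the mitochondrial sequence there were 25 peaks in replicate 1 and 19 in replicate 2, with a median score of 150 in both, the highest score in the lists. No explanation was tested for these peaks. With 2 samples in 1 group, no sample could be set apart from the others and no groups could be compared.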

How the results depend on the processing

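The alternatives without peaks written with a decimal point, without the leading member of each list, with letter-permuted consensuses, and those of the location ratios were chosen after seeing the data. Overlap of replicates was 84.5% with the stronger 50% of peaks. The rank correlation was 0.919 with reciprocal overlap, 0.884 with the stronger 50% of peaks, and Pearson's r of log2 score was 0.908. The promoter share was 31.4% with a 2500 bp window, 30.2% with start sites of all biotypes and 30.6% with the stronger 50%, and its ratio to the genome share 5.65, 4.99 and 12.5. The intron ratio reversed to 0.956 with 2500 bp and 0.943 with the stronger 50%. Genes with a promoter peak were 68.5% with 2500 bp and 57.7% with the stronger 50%. Hotspot coverage was 1.39% with the stronger 50% of hotspots, which holds fewer hotspots by construction. A wider window or added start sites can only raise the promoter share, and a wider window can only raise the share of genes with a promoter peak. Leaving out weaker peaks can only lower that share of genes. The cause of the other shifts was not tested. The other 31 values that answer a comparison stayed within the spread between replicates, or within 1.5 times for counts. Among them were 3 or 4 lists above by distal peaks and 4 or 5 by promoter peaks, which were not always the same lists. For promoter share, genes with a promoter peak and hotspot coverage, each replicate alone lies within that spread by construction. Those values are no test of stability. Motif directions reversed for GATA (1.31 with shuffled peaks, 1.21 relative to permuted words), NF-kB (0.855 with shuffled peaks), NFY (1.31 with all peaks, 1.01 with the stronger 50%) and MEF2 (0.949 with all peaks); the cause was not tested except for GATA, under other observations. By promoter peaks, myeloid genes were above in the lists of replicates 1 and 2 alone (97.8 and 98.1) and B cell genes in that of replicate 2 (99.5). With a 2500 bp window B cell (99.6) and myeloid (99.7) genes were above and T lineage transcription factors (96.0) were not. With no matching on CpG, cell cycle (99.97) and housekeeping (99.95) genes were above, NK cell genes (81.5) were not, and erythroid (1.16) and hepatocyte (0.035) genes were below. With the stronger 50% of peaks cell cycle genes were above (97.8). By distal peaks with no matching on territory, erythroid genes were below (2.45). No paired analysis was possible because there is 1 group. Depth is unknown, so a site without a peak may lie under the caller's limit. The 57.7% against 64.4% of genes with a promoter peak when weaker peaks were left out does not test this, since that share can only fall.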

Other observations

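The gene groups, windows and counts of this part, the test of weak sites, the letter-permuted consensuses and the lists without decimal-point scores were chosen after the data were seen. The remaining tests address patterns already seen, with their outcomes set out before they were run.

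For 17 genes that guide thymocyte migration and survival, chosen with counts per gene in view and including Socs1 of the 20 leading genes, the mean was 15.7 distal shared peaks per gene. All 17 had a promoter peak in both replicates. Besides Socs1, with 44, the pro-apoptotic gene Bcl2l11 had 31, the chemokine receptor gene Cxcr4 24, the thymus-homing receptor gene Ccr9 19, Ccr7 19, the activation marker gene Cd69 18 and the egress receptor gene S1pr1 18. A group of 10 chemokine and cytokine receptor genes used mainly by other lineages had a mean of 5.0. Peak density per Mb was highest on chromosome 11, at 96.6 ± 7.70 (SD, n = 2), and was 18.6 ± 1.24 on X and 0.54 ± 0.10 on Y, in tissue pooled from both sexes.

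Consensus matches changed with peak strength. From the weakest to the strongest quintile of distal shared peaks, CTCF matches rose from 4.69% to 14.5%, CAGCTG from 13.1% to 21.4% and CACCTG from 18.6% to 26.6%. GATA matches went from 7.63% to 5.56%, while RUNX was at 15.4% in the weakest and 15.6% in the strongest quintile. Of 40 letter-permuted words per consensus, the number with a ratio to flanks as high as the consensus was 2 for RUNX, 2 for CAGCTG (highest 3.39), 3 for CACCTG (highest 2.27) and 0 for ETS, TCF7/LEF1 and AP-1.

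Some unmatched peaks lay in dense blocks. In replicate 1, 32 windows of 100 kb held 20 or more peaks without a counterpart, where the median window with any held 3, and in replicate 2 there were 37. These windows held 1.72% and 2.80% of the unmatched peaks. Of the 32, 17 had a median score under 23, the top of the lowest decile, and of the 37 in replicate 2, 11 had one under 19, the top of theirs. The other 15 and 26 windows held a median of 26 and 23 shared peaks, and the weak ones 4 and 15. On chromosome 8, from 113721776 to 113782765, near Adamts18, replicate 1 had 49 unmatched peaks with a median score of 7 and no shared peak. Over its whole territory Adamts18 had 87 distal peaks in replicate 1 and 3 in replicate 2. On chromosome 4, from 147401436 to 147434225, near the zinc finger gene Zfp978, replicate 2 had 49 with 1 shared peak. Other blocks of replicate 2 included 51 unmatched and 33 shared peaks near Cd8a, 39 and 14 near the thyroglobulin gene Tg, 36 and 37 near Sept9, 31 and 29 near Pgpep1l, 28 and 21 near Arid1b, and 27 and 24 near Bcl11b. At Tcf7 both replicates had such a window, with 32 and 31 unmatched peaks.

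For unmatched peaks as a whole, a technical and a biological explanation were weighed. Some were not closed sites in the other replicate, since 27.9% in replicate 1 and 13.7% in replicate 2 overlapped a hotspot of it. Among unmatched peaks of the highest decile by score these shares were 97.4% and 100%. Weak sites near the calling threshold stay open: the share with a counterpart was at least 80.1 percentage points higher in the highest than in the lowest decile by score, but this value was known before the test and does not separate weak open sites from weak noise. Positions drawn at random as the whole cause are argued against by the RUNX consensus, where such positions would give a ratio to flanks of about 1. In unmatched distal peaks it was 1.53 in replicate 2 and 1.76 in replicate 1. The ETS ratio was 1.79 and 1.82, and the CTCF ratio 4.99 and 29.1, in the same order. CTCF matched 0.401% of unmatched distal peaks in replicate 2 and 2.34% in replicate 1, so these sets differed in content. Background with the base composition of peaks was not tested. In distal shared peaks, letter-permuted RUNX words had a median ratio of 1.11 and a highest of 2.36. A different mix of cell types in the tissues stays open, since 2 of 17 lists lay outside the central 95% of random lists by their ratio of distal peaks between replicates, where 3 had been required and at most 1 would have counted against it: T cell receptor genes (405 in replicate 2 against 337 in replicate 1, percentile 98.9), where most of the difference lay at Cd8b1 (28 against 9), Cd2 (52 against 34) and Cd8a (27 against 14), and olfactory receptor genes (377 against 449, percentile 0.01), which mark no cell type of the thymus. Depth is unknown and stays open.

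Sfi1 had 58 distal shared peaks and no promoter peak. Reads shared between near-identical copies may contribute: in the median Sfi1 peak 43.8% of 31-base words occurred at another place on the main chromosomes or unplaced and unlocalized scaffolds, against 0 in each of the other 19 genes of that set. Of the Sfi1 peaks, 100% held a word found elsewhere, against at most 13.7% of peaks in any of the other 19 genes. The median of 43.8% was under the 50% set in advance. The scaffolds were added after a value of 6.25% on the main chromosomes alone was seen, so the explanation stays open. A dense group of T lineage elements also stays open, since 24.1% of Sfi1 peaks had an ETS or RUNX consensus, between the lowest (20.5%) and the median (47.1%) of the others. Copies missing from the reference were not tested.

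The GATA consensus was less frequent in distal peaks than in flanks. Base composition may account for this: distal peaks were 50.8% G and C against 45.5% in flanks, and the GATA ratio divided by the median of 40 letter-permuted consensuses was 1.21. Of the 40 words, 4 had a ratio as high as GATA. No biological explanation was tested for GATA.

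Peaks whose scores were written with a decimal point often overlapped another peak of their own list. They made up 6.78% of peaks in replicate 1 and 10.1% in replicate 2, and 51.2% and 48.3% of them overlapped another peak of their own list, against 3.5% and 4.88% of the rest. Of these peaks 37.7% and 35.9% had a counterpart in the other replicate, against 69.4% and 79.1%. Their scores were lower, with medians of 27 and 24 against 49 and 44. Other peaks of the same scores had a counterpart in 37.6% and 55.2% of cases, so the lower share goes with the score in replicate 1 and is below it in replicate 2. Without them, 73.6% of peaks were shared.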
